A study of Solanum lycopersicum with 12 samples.

How the data were processed

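Gene expression was measured with an Affymetrix tomato array in whole hydroponic tomato plants that had 6 leaves. Plants of 2 genotypes, the cultivar Moneymaker and PI365967, known as a salt-tolerant wild tomato, stood for 5 h in nutrient solution with 0 or 200 mM NaCl. The labels give Solanum lycopersicum as the organism of all samples. Each of the 4 groups had 3 arrays, and each array took the pooled RNA of 3 plants, so that the replicates are separate pools of plants. There were 12 arrays in all.

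The values analysed are the authors' deposited intensity values, with 1 linear intensity per probe set and array. The background correction and the summary of probes to probe sets behind them are not given in the sources used here. Their medians ran from 332.8 to 633.2 over the arrays, a range of 0.93 in log2, so they had not been scaled to a common level. The authors also deposited, for each genotype, a second set of log2 values of the same arrays for part of the probe sets (8085), made by a method not given in the sources used here. From these the authors computed a SAM table (significance analysis of microarrays, unpaired, with 100 permutations). For each probe set it lists the authors' SAM score, the difference of mean log2 values, the ratio of salt over control, and a q-value in percent that the file headers place in a column of other settings. These tables served only as alternatives.

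Intensities became log2(value + 16). Because the array medians differed by more than 0.2 in log2, quantile normalization of the 12 arrays was added, as laid down before the data were examined. The 108 control probe sets of the array stayed out of the tests, which left 10101 probe sets. Linear models with a mean per group were fitted to all 12 arrays with limma (lmFit and eBayes; 8 residual degrees of freedom, 3.11 prior degrees of freedom), without covariates. There were 6 contrasts: the salt effect in each genotype, the difference of the salt effects (PI365967 minus Moneymaker), the genotype difference (PI365967 minus Moneymaker) without and under salt, and the mean of both salt effects. All tests were two-sided. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested. Values after a ± sign are standard errors of a log2 difference from limma, with n = 3 arrays per group. The number of arrays limits the precision: the median standard error was 0.114 for a salt or genotype effect and 0.161 for the difference of salt effects.

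On simulated data with 50 probe sets per step, the procedure was tested for recovery and false calls. A change of 1 in log2 was recovered in 96% of cases for the salt effect in Moneymaker, 86% for PI365967 and 78% for the difference of salt effects. A change of 0.5 was recovered in 34%, 52% and 30%. False calls made up 3.85% to 7.78% of the calls. The simulation gave each probe set the same SD and number of arrays in every group. Its gaps between the 2 genotypes therefore come from the probe sets and noise drawn. The noise was independent between probe sets. Each simulated data set held all steps together, and only 50 of 10101 probe sets changed per step. In the real data 57% and 47.3% were called for salt in Moneymaker and PI365967, so recovery there can differ.

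The annotation pairs 909 probe sets with a gene symbol, and 702 of these carry a gene name rather than a locus number (626 distinct names); it gives no descriptions. Genes were named by a rule set in advance. For each salt effect, these were the 10 largest rises and 10 largest falls among called probe sets with a name whose 3 salt arrays all lay on one side of the 3 control arrays. Outside the gene lists, a gene with several probe sets was represented by that with the largest mean signal. A larger change on another of its probe sets, as for FESOD, did not enter there. For the difference of salt effects the rule took the 8 largest called differences each way, and for each genotype difference the 6 largest each way. It added up to 4 called members per gene list. A list member with several probe sets was represented by that with the largest called salt change in either genotype, so its other probe sets can have changed less. A probe set whose identifier ends in _x_at or _s_at can take signal from related transcripts, which is stated where one is named.

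Of 23 gene lists, 20 were laid down in advance as word patterns. The annotation holds symbols without descriptions, so members were completed by symbol when it was read, before expression was analysed. The list laid down for histones and cell cycle came to hold cyclin and cyclin-dependent kinase genes and PCNA, and no histone gene, and is called cell cycle. The patterns gave 121 memberships and the symbols 219 more. The lists for gibberellin, for carotenoid and isoprenoid synthesis and for 14-3-3 proteins were added at that point. Each list with 5 or more probe sets was tested against all other probe sets with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over lists within a contrast, with camera at an estimated correlation and fry beside it.

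A background level was set after the data had been seen: for each array, the highest of its 17 empty tag control probe sets, which came to 4.72 to 5.39 in normalized log2. On each array 7.4% to 12.8% of probe sets lay at or below it. A fold against a group that lay wholly at this background is given as a lower bound.

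The replicate numbers in the labels were checked for pairing, as the correlation of deviations from group means between arrays of the same number. This lay at 0.116 to 0.162 for the controls of the 2 genotypes, against at most 0.007 for other numbers. Deviations from a mean of 3 arrays sum to 0, so high values for the same number push the others down. Arrays of unlike number reached 0.151 between the PI365967 groups and 0.108 between the 2 salt groups. The numbers may pair the genotype difference without salt, but pairing is not established. With the replicate number as a block, that difference had 3660 called probe sets, against 3718 without the block.

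Alternatives covered the log2 offset (1 and 64), the normalization between arrays (none, median centring), filters on dim probe sets, the variance model, array weights, the replicate block, each array left out in turn, the groups in the fit, the threshold, SAM, and the set test and members of the lists. Chosen after seeing the data were the authors' second log2 values, a restriction to the probe sets the authors kept, and lists with pattern-matched members alone. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.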

Results

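The data comprised 12 arrays in 4 groups of 3: Moneymaker and PI365967 plants after 5 h without salt or with 200 mM NaCl. Replicate arrays correlated across probe sets at Pearson's r of 0.9909 to 0.9946, and the median SD between replicates was 0.107 to 0.129 in log2. The first principal component, with 53.2% of the variance, set salt arrays above control arrays within each genotype, and the second, with 33.9%, set PI365967 apart from Moneymaker. Both components mixed salt and genotype. Within each treatment the first was lower in PI365967, and within each genotype the second was higher under salt. Among the array's control transcripts, 25S ribosomal RNA lay 1.86 higher in log2 under salt in Moneymaker and 0.66 higher in PI365967, where 1 of the 3 salt arrays lay within the range of the controls, while the 3′ and 5′ probe sets of GAPDH differed by 0.04 to 0.12 in all groups.

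The first comparison asked which genes responded to salt in Moneymaker. AOS, allene oxide synthase of jasmonate synthesis, rose 30.3-fold (log2 4.92 ± 0.19, adjusted p = 8.12e-09), and GolS-1, galactinol synthase, rose 23.1-fold (log2 4.53 ± 0.27, adjusted p = 1.09e-07). NCED1, the 9-cis-epoxycarotenoid dioxygenase of abscisic acid (ABA) synthesis, rose 12.0-fold from a mean log2 signal of 8.86 to 12.45, and ACS2, an ACC synthase of ethylene synthesis, rose 12.4-fold. The subtilase gene SBT1 fell by 3.63 ± 0.22 on the log2 scale, and the phosphate transporter gene PT2 fell by 3.08 ± 0.30.

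Other named rises in Moneymaker were those of the small heat shock gene HSP17.4 (log2 4.05), the transcriptional coactivator gene ER24 (3.98), SNF4, a subunit of the SnRK1 kinase complex (3.96), DREB1 (3.37), ER5 (3.19) and the lysyl-tRNA synthetase gene LysRS (3.11). SNF4 lay at background in the controls, and its rise was at least 13.8-fold. Falls included TCP3, a TCP transcription factor gene (−3.05), the peroxidase gene TPX2 (−2.96), cevi19 (−2.87, a probe set that can take signal from related transcripts), the gibberellin 20-oxidase gene GA20OX1 (−2.85), yfe37 (−2.73), the expansin gene exp9 (−2.66), GP1 (−2.49) and Dif54 (−2.45). Over all 10101 probe sets, 2625 rose and 3131 fell, of which 826 and 714 changed at least 2-fold. Without normalization between arrays 3534 were called, 28.4% of them higher, against 5756 and 45.6% here.

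Among gene lists in Moneymaker, all 6 probe sets of ABA- and water-stress-induced proteins rose, among them the dehydrin gene TAS14 (3.03-fold), LE16, a lipid transfer protein gene (log2 1.54), and LEA14 (1.04). Camera called the list at an adjusted p = 0.000444, with adjusted p = 0.0763 with an estimated correlation. Of the 22 WRKY, NAC, bZIP and DREB transcription factor probe sets, 17 rose, none fell and 5 were not called (adjusted p = 2.66e-06; adjusted p = 0.0763 with an estimated correlation), with AREB1 (3.08), the NAC gene JA2 (2.58) and the bZIP gene abz1 (2.57) as examples. Of the 41 ethylene probe sets, 25 rose, 8 fell and 8 were not called (adjusted p = 0.00066; adjusted p = 0.114 with an estimated correlation). ACS6 (2.95), EREB (2.94) and PTI5 (2.77), the last an ethylene-response-type transcription factor, were among those that rose. Of the 6 polyamine probe sets, which cover 3 genes with 4 for adc1 alone, 5 rose and 1 was not called, with the arginine decarboxylase probe sets adc1 (1.46) and ADC (0.50) among them (adjusted p = 0.00114; adjusted p = 0.255 with an estimated correlation). The ADC call was lost without normalization between arrays (0.24). Of the 18 probe sets of signalling kinases and calcium sensors, 8 rose, none fell and 10 were not called (adjusted p = 0.0225; adjusted p = 0.32 with an estimated correlation). Examples were MPK3 (1.86, a probe set that can take related signal), the NADPH oxidase gene Wfi1 (1.26) and MAPKKKalpha (0.64, a call lost without normalization between arrays, at 0.42). That list's adjusted p was 0.0961 with 1 probe set per gene and 0.0534 without probe sets open to related signal.

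Cell wall genes fell in Moneymaker: of 48 probe sets 30 fell, 6 rose and 12 were not called (adjusted p = 0.000443), and this was the list call that also held with an estimated correlation (adjusted p = 0.0273). Expansin EXP5 fell by 2.25, the endoglucanase gene cel7 by 1.97, and the xyloglucan endotransglucosylase/hydrolase gene XTH16 by 1.75 and 2.27 on 2 probe sets, while the beta-galactosidase gene TBG4 rose by 2.00. Of the 9 photosynthesis probe sets 8 fell and 1 was not called, among them the chlorophyll a/b-binding protein genes CAB5 (−1.24) and CAB4 (−0.64), the plastocyanin gene PETE (−1.09) and PsbQ (−0.65). Camera called this list at an adjusted p = 0.00228, with adjusted p = 0.32 with an estimated correlation. The root-leaning list of nutrient transporters and root peroxidases moved the same way, with 7 of 12 probe sets lower and 2 higher and a median of −0.72, without a call (adjusted p = 0.0858). Its members included the ammonium transporter gene AMT1-2 (−2.04) and NRAMP1 (−1.50). Counts adjusted over the list alone were 26 risen ethylene probe sets, 18 risen transcription factors, 7 risen cell wall probe sets and 9 fallen carotenoid and isoprenoid probe sets, and equal to the counts given here for all other lists in Moneymaker.

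The remaining lists had no camera call in Moneymaker. Ion transport had 4 probe sets higher, 1 lower and 1 not called: NHX1, the vacuolar sodium/proton exchanger gene, rose by 1.67 ± 0.13, the potassium channel gene LKT1 rose by 0.84, and LHA2, a plasma membrane proton pump gene, fell by 0.51. ABA synthesis and signalling had 3 higher and 2 lower of 8, with the aldehyde oxidase gene AO1 at −1.26. Jasmonate and wound response had 9 higher and 6 lower of 27, with loxD, a lipoxygenase gene, at 2.59, LEJA1 at −2.23 and OPR1 at −1.74. Solute genes had 4 higher and 3 lower of 16, with the proline transporter gene ProT1 at 0.82, the invertase gene LIN8 at −1.10 and IMP3 at −0.85. Heat shock proteins had 5 higher and 2 lower of 9, with MTSHP at 2.56, HSP17-6 at 0.63 and vis1 at 1.26. Pathogenesis-related proteins had 6 higher and 3 lower of 14, with the chitinase genes CHI17 (2.09) and CHI14 (1.19) and PR-P2 (1.46) higher. Antioxidant enzymes had 6 higher and 10 lower of 24, with a median of −0.17 and a downward test but a mean of 0.13. There the alternative oxidase gene AOX1a (2.22) and GST-T4 (1.07) rose and the thioredoxin gene CITRX fell (−1.26), and of the 2 probe sets of the iron superoxide dismutase gene FESOD 1 rose (3.14) and the other was called lower. Lists with more falls were auxin response (6 lower and 1 higher of 16, RSI-1 −1.63, IAA16 −1.17), gibberellin (5 lower of 8, 3OH-2 −1.42, GA3ox1 −1.26) and cell cycle (7 lower of 11, PCNA −1.45). Ribosomal proteins (3 lower of 6, rpl38 −0.46), phenylpropanoids (3 lower of 5, DFR −1.87, CHS2 −1.06), carotenoids and isoprenoids (7 lower and 5 higher of 19, CrtR-b1 1.51, VDE −1.34) and 14-3-3 proteins (3 lower of 7, tft8 −0.42, TFT3 −0.34) followed. Both aquaporin probe sets fell (Aqp2 −1.40, TIP −0.41), a list too short to test; without normalization between arrays the calls for HSP17-6 (0.43) and TFT3 (−0.52) were lost, and the TIP call was lost when any 1 of 3 arrays was left out (−0.40 to −0.31).

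**Figure D1:**
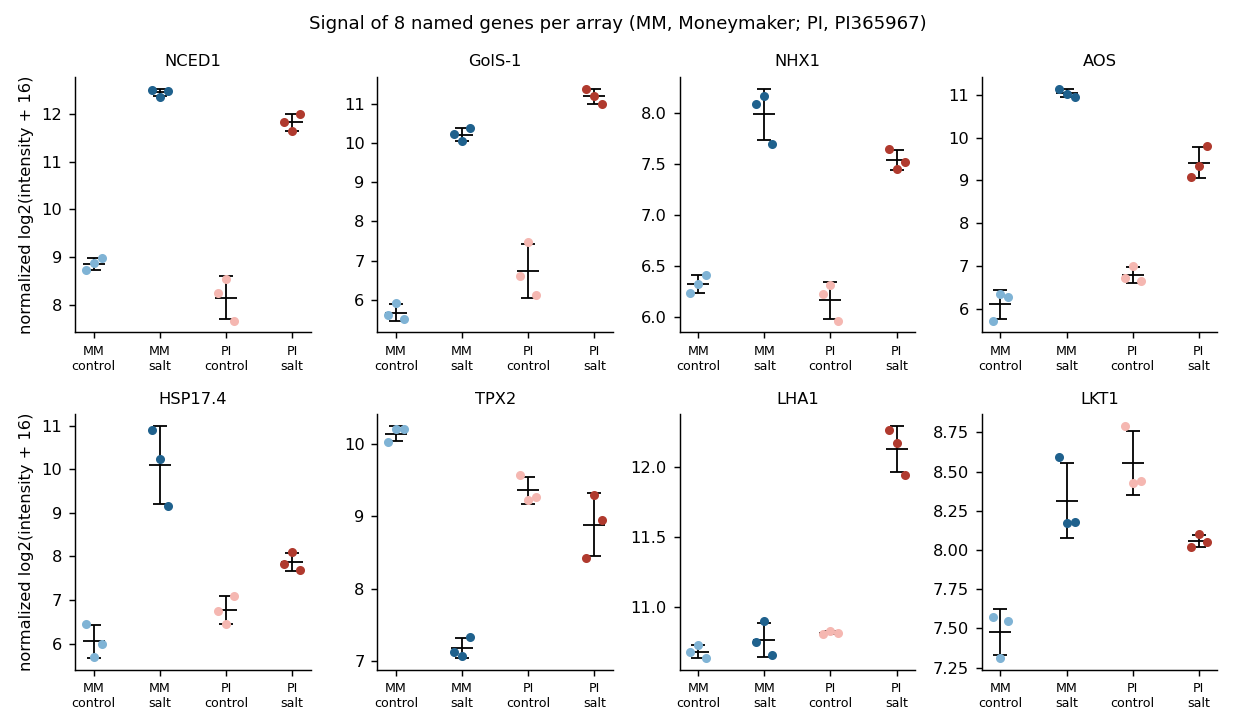
Signal of 8 named genes as normalized log2(intensity + 16) on each array (points), with the group mean and SD (bars, n = 3 arrays) for Moneymaker (MM) and PI365967 (PI) without and with salt. NCED1 went from 8.86 to 12.45 in Moneymaker and from 8.16 to 11.82 in PI365967, while LHA1 went from 10.68 to 10.77 in Moneymaker (without normalization between arrays its change there was −0.11) and from 10.82 to 12.12 in PI365967. The axes do not start at 0.

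The second comparison asked the same of PI365967. GolS-1 rose 21.9-fold (log2 4.45 ± 0.27, adjusted p = 2.73e-07), SNF4 18.3-fold (log2 4.19 ± 0.14, adjusted p = 8.45e-09) and NCED1 12.7-fold (log2 3.66 ± 0.18, adjusted p = 8.05e-08). ACS2 rose by 3.29, DREB1 by 2.83, AOS by 2.63 and ER5 by 2.62 in log2. The ethylene receptor gene ETR6 (2.55), the chitinase gene CHI17 (2.45) and PPCK1, a kinase gene of phosphoenolpyruvate carboxylase (2.44), completed the 10 largest named rises. SBT1 fell by 2.69 ± 0.22, GA20OX1 by 2.44 ± 0.22 and exp9 by 2.40 ± 0.12.

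Further named falls in PI365967 were TCP3 and Dif54 (both −2.36), cel7 (−2.30), GP1 (−2.25), XTH16 (−2.24) and yfe37 (−2.13). The gibberellin 20-oxidase gene 20ox-3 reached background under salt, a fall of at least 3.44-fold. Over all probe sets 2353 rose and 2428 fell, of which 511 and 525 changed at least 2-fold. Without normalization between arrays 1983 were called, against 4781 here.

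Of the gene lists in PI365967, all 6 ABA- and water-stress probe sets rose (adjusted p = 0.00131; adjusted p = 0.115 with an estimated correlation), with TAS14 at 1.08, LEA14 at 0.86 and LE16 at 0.69. Transcription factors had 14 higher, none lower and 8 not called (adjusted p = 0.000114; adjusted p = 0.115 with an estimated correlation), with AREB1 at 2.13, abz1 at 2.00 and JA2 at 1.74. Polyamine synthesis had 5 of 6 higher (adjusted p = 0.00475; adjusted p = 0.278 with an estimated correlation), with adc1 at 1.59 and ADC at 0.21, a call that was lost without any 1 of 10 arrays (0.18 to 0.24), with median centring (0.14) and without normalization (0.22). With 1 probe set per gene this list was too short to test. Ethylene had 16 higher, 7 lower and 18 not called (adjusted p = 0.032; adjusted p = 0.278 with an estimated correlation), with EREB at 0.98, and without replicate 3 of the salt arrays its adjusted p was 0.0779. Cell wall genes had 25 lower, 8 higher and 15 not called (adjusted p = 0.00475; adjusted p = 0.103 with an estimated correlation), with EXP5 at −0.77 and TBG4 at 2.43.

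Cell cycle genes fell in PI365967, with 8 of 11 lower and none higher (adjusted p = 0.00475; adjusted p = 0.378 with an estimated correlation). PCNA, the DNA polymerase clamp gene, fell by 1.64, CDKB2, a cyclin-dependent kinase gene, by 1.43, and the cyclin gene CycA1 by 1.05. CycB2 (−0.93) was also called as lower but rose by 0.69 in the authors' second log2 values. All 6 ribosomal protein probe sets fell (adjusted p = 0.0198; adjusted p = 0.132 with an estimated correlation), among them rpl38 (−0.58), RPL8 (−0.32) and RPL3 (−0.21), whose probe set can take related signal and whose call was lost without any 1 of 4 arrays (−0.21 to −0.18). Gibberellin had 5 of 8 lower (adjusted p = 0.0252; adjusted p = 0.152 with an estimated correlation). The root-leaning list had 6 of 12 lower and none higher (adjusted p = 0.0158; adjusted p = 0.115 with an estimated correlation), with PT2 at −1.56 and AMT1-2 at −0.95, and photosynthesis had 4 of 9 lower and none higher without a call (adjusted p = 0.0746). With pattern-matched members alone the adjusted p of the root-leaning list was 0.168.

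Other lists in PI365967 had no camera call. In ion transport 2 probe sets rose, 1 fell and 3 were not called: NHX1 rose by 1.38 ± 0.13, LHA1, a plasma membrane proton pump gene, rose by 1.30 ± 0.09, and LKT1 fell by 0.50 ± 0.13. Higher and lower counts were 7 and 2 of 16 for solutes (ProT1 0.91), 6 and 2 of 9 for heat shock proteins (MTSHP 1.20, HSP17-6 0.99), and 6 and 3 of 14 for pathogenesis-related proteins (CHI14 1.76, P69B −1.51). They were 2 and 3 of 8 for ABA synthesis (AO1 −0.99, TAO3 −0.60) and 5 and 8 of 27 for jasmonate and wound response (loxD 1.39, LEJA1 −1.80, OPR1 −1.18). Signalling had 6 and 5 of 18, the 5 including PRK2, which lay at background in all 4 groups and whose call (−0.44) was lost under 6 of the alternatives. Antioxidant enzymes had 5 and 6 of 24 with a median of −0.13 and a downward test but a mean of 0.10 (AOX1a 0.96, CITRX −1.19). Auxin response had 4 lower of 16 (IAA16 −1.24, RSI-1 −1.13, and IAA27 −1.17, which can take related signal). Carotenoids and isoprenoids had 5 and 8 of 19 (CrtR-b1 1.84, Psy1 1.35, HMGR −1.35), phenylpropanoids 1 and 3 of 5 (CHS2 −2.12, hqt 0.60), and 14-3-3 proteins 3 lower of 7 (tft8 −0.43, TFT6 −0.43). Both aquaporin probe sets fell (Aqp2 −0.84, TIP −0.44), the TIP call being lost without any 1 of 3 arrays (−0.40 to −0.33). Without normalization between arrays the calls for TAO3 (−0.50), hqt (0.66), tft8 (−0.37), TFT6 (−0.39), TIP (−0.46), rpl38 (−0.50), RPL8 (−0.33) and RPL3 (−0.23) were lost. Counts adjusted over the list alone were 3 fallen auxin, 8 fallen ethylene, 2 risen phenylpropanoid, 7 fallen root-leaning, 6 fallen signalling and 1 fallen transcription factor probe sets, and equal for all other lists in PI365967.

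**Figure D2:**
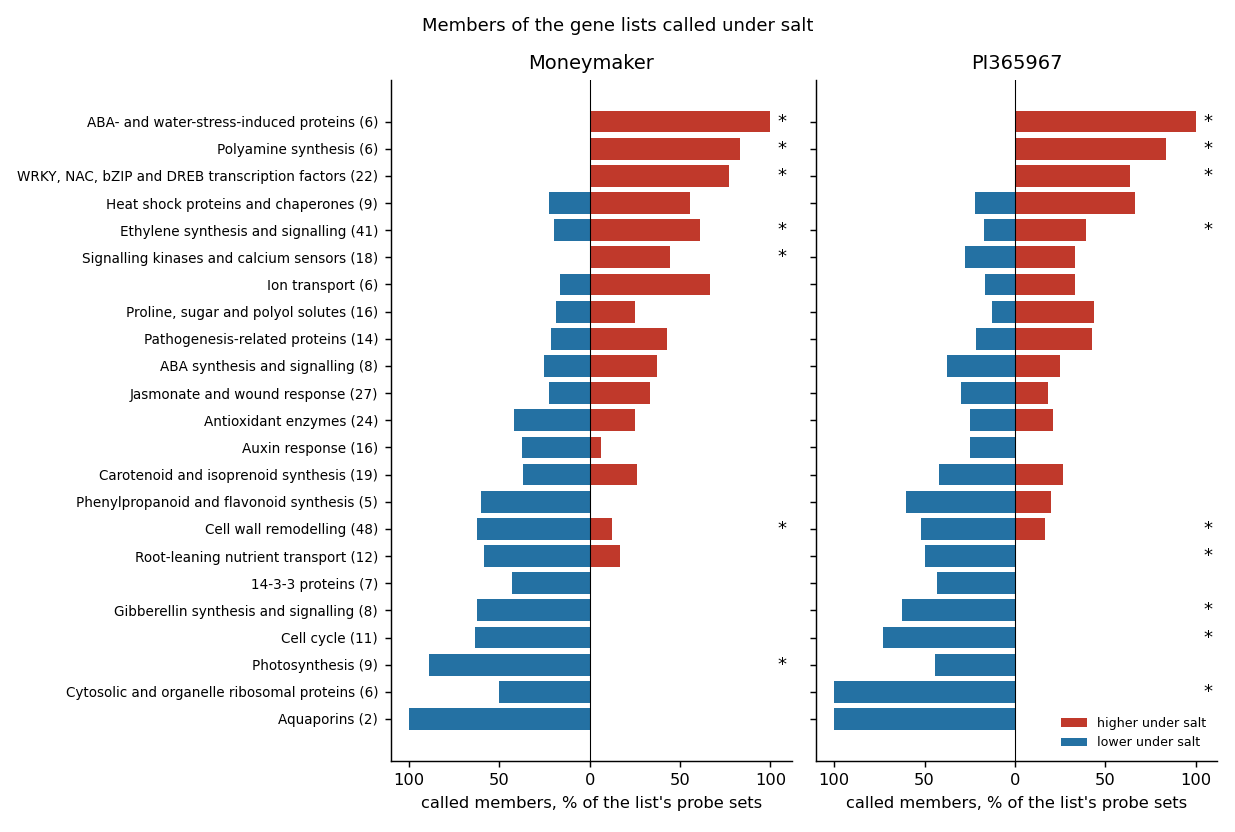
Percent of each list's probe sets called higher (red, to the right) or lower (blue, to the left) under salt in Moneymaker and PI365967, with the number of probe sets in brackets and a star for a camera adjusted p under 0.05 at the preset correlation. All 6 ABA- and water-stress probe sets rose in both genotypes, and 30 of 48 cell wall probe sets fell in Moneymaker against 25 in PI365967.

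The genotypes shared most of these changes. GolS-1, SNF4, NCED1, ACS2, DREB1, AOS and ER5 were among the 10 largest named rises in both, and SBT1, GA20OX1, exp9, TCP3, Dif54, GP1 and yfe37 among the 10 largest named falls. Over all probe sets 1767 rose in both, against 611.5 if the calls were independent, and 1991 fell in both, against 752.6. Opposite calls were made for 37 probe sets that rose in Moneymaker and fell in PI365967 and 30 the other way. Across 10101 probe sets, which are not independent replicates, the salt effects correlated at Pearson's r = 0.837 and Spearman's rho = 0.788. The mean of both salt effects was called for 6442 probe sets, 3043 higher and 3399 lower, and without normalization for 3885. By list, that mean was called higher by camera for ABA- and water-stress proteins (6 of 6), transcription factors (17 of 22), ethylene (25 of 41) and polyamine synthesis (5 of 6), with adjusted p from 1.36e-05 to 0.00216. With an estimated correlation their adjusted p were 0.101, 0.101, 0.138 and 0.222. It was called lower for cell wall genes (29 of 48, adjusted p = 0.00152), photosynthesis (8 of 9, 0.00777), cell cycle (9 of 11, 0.0163), and ribosomal (6 of 6), gibberellin (6 of 8) and root-leaning probe sets (7 of 12, each 0.031). With an estimated correlation these adjusted p were 0.0504, 0.416, 0.442, 0.16, 0.16 and 0.138. Adjusted over the list alone, 30 cell wall probe sets fell, and the counts of the other called lists were the same.

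**Figure D3:**
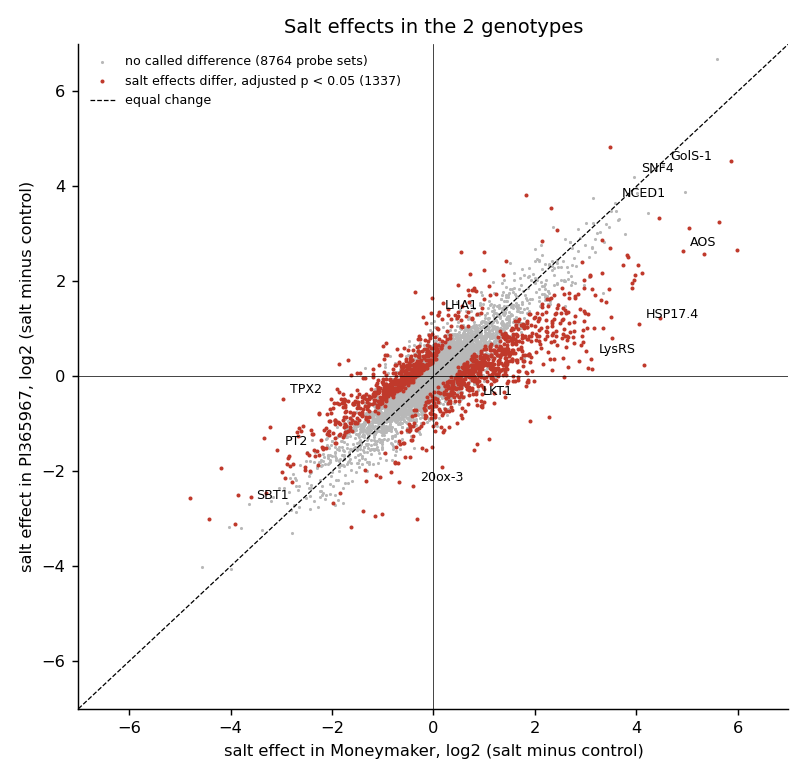
Salt effect (log2, salt minus control) of each of 10101 probe sets in Moneymaker (horizontal axis) and PI365967 (vertical axis), with red points for the 1337 whose effects differed between genotypes. Genes near the dashed line of equal change include NCED1 (3.58 and 3.66), and HSP17.4 (4.05 and 1.11) and TPX2 (−2.96 and −0.47) lie away from it.

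The third comparison asked where the response to salt differed between genotypes, by the interaction term. HSP17.4 rose by 4.05 in Moneymaker and 1.11 in PI365967, a difference of −2.95 ± 0.52 (adjusted p = 0.00433), and LysRS rose by 3.11 in Moneymaker against a value of 0.37 in PI365967 that was not called (difference −2.73 ± 0.31, adjusted p = 0.000368). AOS (−2.29 ± 0.27) and the ethylene-related genes ACS6 (−2.22 ± 0.35), PTI5 (−2.05 ± 0.29) and EREB (−1.96 ± 0.25) also rose less in PI365967. LHA1 rose in PI365967 by 1.30 against a value of 0.09 in Moneymaker that was not called, a difference of 1.21 ± 0.13 (adjusted p = 0.00027). LKT1 rose in Moneymaker and fell in PI365967 (0.84 and −0.50, difference −1.33 ± 0.19, adjusted p = 0.00122), though neither change was called without normalization between arrays (0.50 and −0.44). TPX2 fell by 2.96 in Moneymaker against a value of −0.47 in PI365967 that was not called (difference 2.49 ± 0.26, adjusted p = 0.000268).

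Further negative differences were those of 20ox-3 (−1.92 as measured, with PI365967 at background under salt, where its fall has only the lower bound given above) and ER24 (−1.85). Positive ones were PT2 (1.52), EXP5 (1.47), CEVI57 (1.35), the expansin gene EXP1 (1.34), the xyloglucan endotransglycosylase gene XET2 (1.24) and cevi19 (1.15, open to related signal). The calls for PT2, CEVI57 and XET2 were lost when any 1 of 8, 9 and 9 arrays was left out, with values of 1.24 to 1.62, 1.28 to 1.43 and 1.04 to 1.29. With the replicate block, whose numbers may pair the controls, those for PT2 (adjusted p = 0.0635) and CEVI57 (adjusted p = 0.0561) were lost too. An offset of 1 also ended the calls for PT2 (adjusted p = 0.0629) and XET2 (adjusted p = 0.0529). That for CEVI57 was lost with an offset of 64 (0.80, adjusted p = 0.08) and with median centring (1.14, adjusted p = 0.0982). In PI365967 the smaller rises of HSP17.4 (0.95 to 1.12), ACS6 (0.41 to 0.70) and PTI5 (0.58) lost their calls without any 1 of 4, 3 and 1 arrays. Over all probe sets 621 differences were positive and 716 negative. Of the positive ones 484 fell in Moneymaker and 166 rose in PI365967, and of the negative ones 601 rose in Moneymaker and 150 fell in PI365967. The share of positive calls was 46.4%, against 35.4% with median centring and 60.3% of 292 calls without normalization.

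By list, ABA- and water-stress proteins had a median difference of −0.43, with 2 of 6 lower (LE16 −0.85; adjusted p = 0.0346; adjusted p = 0.271 with an estimated correlation). That adjusted p was 0.0665 without Moneymaker control replicate 2, 0.0611 without PI365967 control replicate 2, and 0.0616 with the replicate block. Transcription factors had a median of −0.45, with 8 of 22 lower (AREB1 −0.95, JA2 −0.84; adjusted p = 9.37e-05; adjusted p = 0.165 with an estimated correlation). Signalling had a median of −0.33, with 4 of 18 lower (MPK3 −1.42, open to related signal; adjusted p = 0.00013; adjusted p = 0.165 with an estimated correlation). Ethylene had a median of −0.10, or 0.13 without normalization, where the median of all probe sets was 0.30, with 10 of 41 lower and 1 higher (adjusted p = 0.00233; adjusted p = 0.165 with an estimated correlation). Cell wall genes had a median of 0.31, with 11 of 48 higher and 1 lower (adjusted p = 0.0031; adjusted p = 0.0849 with an estimated correlation), and with pattern-matched members alone a median of −0.13 and an adjusted p of 0.823. Photosynthesis had a median of 0.34, with 2 of 9 higher (PETE 0.83; adjusted p = 0.0021; adjusted p = 0.473 with an estimated correlation). Adjusted over the list alone, 3 ABA- and water-stress, 9 transcription factor, 7 signalling and 10 ethylene probe sets were lower, and 17 cell wall (with 2 lower) and 7 photosynthesis probe sets were higher. The other lists had no camera call, with adjusted p from 0.0685 for polyamine synthesis, of which no probe set was called (4 lower adjusted over the list alone), to 0.82 for gibberellin. Jasmonate and wound response had 4 of 27 lower and 2 higher (loxD −1.19, OPR1 0.56; adjusted p = 0.0868). Over all probe sets the SD of the salt effects was 0.822 in Moneymaker and 0.662 in PI365967. The slope through the origin of PI365967 on Moneymaker was 0.674. These list tests did not take such generally smaller changes into account. Whether a list differed beyond them was not tested.

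The fourth comparison asked how the genotypes differed without salt. PR1b1, a pathogenesis-related protein gene, lay 6.48 ± 0.51 lower in log2 in PI365967 (13.03 in Moneymaker, 6.55 in PI365967, adjusted p = 2.97e-06). CEVI57 (−5.20 ± 0.28), the aldehyde oxidase gene TAO2 (−4.62 ± 0.17), cathDInh, a cathepsin D inhibitor gene (−3.47 ± 0.39), pip1 (−3.40 ± 0.35) and psi14A (−3.27 ± 0.25) were also lower. Higher in PI365967 were the proline transporter gene ProT3 (2.49 ± 0.15, adjusted p = 4.18e-07), Mdip1 (2.16 ± 0.17), BR1, a xyloglucan endotransglycosylase gene (1.88 ± 0.23), the small heat shock genes ER-SHSP (1.83 ± 0.23) and vis1 (1.75 ± 0.25), and MT3 (1.81 ± 0.14). The array's probes come from cultivated tomato sequence, so a lower signal in PI365967 can be a mismatch of sequence.

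Of the 14 pathogenesis-related probe sets, 10 were lower in PI365967 without salt, 1 was higher and 3 were not called (CHI14 −1.71, PR-P2 −1.66; adjusted p = 0.000722; adjusted p = 0.786 with an estimated correlation). Antioxidant enzymes had 10 of 24 higher and 1 lower (FESOD 1.19, GST-T4 0.92, AOX1a 0.82; adjusted p = 0.0403; adjusted p = 0.372 with an estimated correlation), with a median of 0.21, or −0.05 without normalization, where the median of all probe sets was −0.22. Both lists had the same counts adjusted over the list alone, and the other lists had adjusted p of 0.19 to 0.945. Over all probe sets 1935 were higher and 1783 lower in PI365967, or 272 and 374 at 2-fold or more. Without normalization between arrays 1585 were called, 18.7% of them higher against 52.0% here. With the replicate block 3660 were called.

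**Figure D4:**
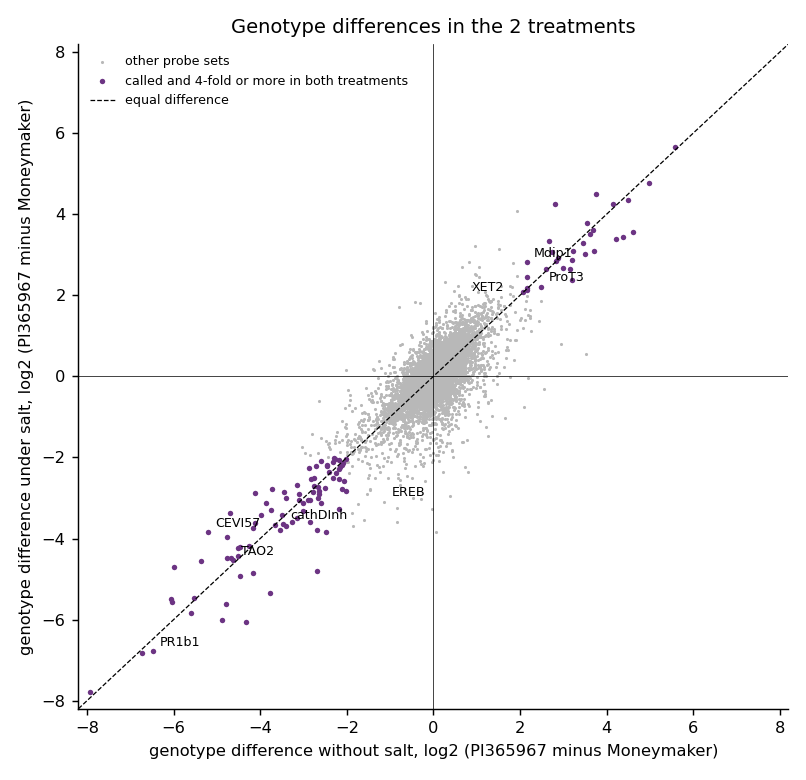
Genotype difference (log2, PI365967 minus Moneymaker) of each probe set without salt (horizontal axis) and under salt (vertical axis), with purple points for the 115 called at 4-fold or more in both treatments. Of these 84 lie lower in PI365967, among them PR1b1 (−6.48 and −6.78), and 31 higher, among them ProT3 (2.49 and 2.21).

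The fifth comparison asked how the genotypes differed under salt. PR1b1 (−6.78 ± 0.51, adjusted p = 1.53e-06), CEVI57 (−3.85), pip1 (−3.70), cathDInh (−3.65) and psi14A (−3.60) were again lower in PI365967, and TAO2 was at background there, at least 16.7-fold lower. Mdip1 (2.82), ProT3 (2.21), MT3 (2.21), ER-SHSP (1.99), XET2 (1.97) and LOX1.1, a lipoxygenase gene (1.87), were higher. Across probe sets, which are not independent replicates, the genotype differences without and under salt correlated at Pearson's r = 0.774 and Spearman's rho = 0.634.

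Photosynthesis probe sets were higher in PI365967 under salt, 8 of 9 with 1 not called (CAB5 1.40, PETE 1.34; adjusted p = 0.00408; adjusted p = 0.471 with an estimated correlation). Cell wall genes had 22 of 48 higher and 7 lower (EXP1 1.46, EXP5 1.31; adjusted p = 0.0348; adjusted p = 0.198 with an estimated correlation). Ethylene had 21 of 41 lower and 4 higher (EREB −3.09, ACS6 −2.09, PTI5 −2.06; adjusted p = 0.0016; adjusted p = 0.198 with an estimated correlation). Transcription factors had 9 of 22 lower and 1 higher (adjusted p = 0.00578; adjusted p = 0.371 with an estimated correlation), and signalling 8 of 18 lower and 1 higher (MPK3 −1.49, open to related signal; adjusted p = 0.0348; adjusted p = 0.471 with an estimated correlation). Pathogenesis-related proteins had 8 of 14 lower and 1 higher (P69B −2.37; adjusted p = 0.0262; adjusted p = 0.736 with an estimated correlation). These 6 lists had the same counts adjusted over the list alone, and the other lists had adjusted p of 0.0585 to 0.98. Over all probe sets 2686 were higher and 2275 lower in PI365967, and 2020 were called without normalization between arrays.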

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

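All tests in this part were set before their results were seen, except the background level and the lists with pattern-matched members alone, which were chosen after the data were seen, and the patterns themselves were found in the same data. The salt effect differed between genotypes, by the interaction term, for 1337 probe sets and for the following named genes, as log2 PI365967 minus Moneymaker. Lower in PI365967 were HSP17.4 (−2.95), LysRS (−2.73), AOS (−2.29), ACS6 (−2.22), PTI5 (−2.05), EREB (−1.96), 20ox-3 (−1.92 as measured, with PI365967 at background under salt), ER24 (−1.85), MPK3 (−1.42, open to related signal), MTSHP (−1.35), LKT1 (−1.33), AOX1a (−1.26), loxD (−1.19), CHS2 (−1.07), AREB1 (−0.95), HMGR (−0.91), LE16 (−0.85), JA2 (−0.84), CDKB2 (−0.78), GST-T4 (−0.71) and CycA1 (−0.65). Higher in PI365967 were LHA2 (0.42), IMP3 (0.51), OPR1 (0.56), Aqp2 (0.57), hqt (0.65), PETE (0.83), Psy1 (0.86), PPCK1 (1.01), AMT1-2 (1.09), cevi19 (1.15, open to related signal), LHA1 (1.21), XET2 (1.24), EXP1 (1.34), CEVI57 (1.35), EXP5 (1.47), PT2 (1.52) and TPX2 (2.49). The calls for CEVI57 and XET2 were lost when any 1 of 9 arrays was left out (1.28 to 1.43 and 1.04 to 1.29), and that for PT2 when any 1 of 8 was (1.24 to 1.62). With the replicate block the calls for PT2 (adjusted p = 0.0635) and CEVI57 (adjusted p = 0.0561) were lost as well. The same held with an offset of 1 for PT2 (adjusted p = 0.0629) and XET2 (adjusted p = 0.0529). It also held for CEVI57 with an offset of 64 (adjusted p = 0.08) and with median centring (adjusted p = 0.0982). Median differences of the lists that camera called were −0.43 for ABA- and water-stress proteins, 0.31 for cell wall remodelling, −0.10 for ethylene, 0.34 for photosynthesis, −0.33 for signalling and −0.45 for transcription factors. Without normalization between arrays, where the median of all probe sets was 0.30, they were −0.20, 0.56, 0.13, 0.46, −0.04 and −0.20 in the same order. With an estimated correlation none of these list calls held (adjusted p = 0.271, 0.0849, 0.165, 0.473, 0.165 and 0.165 in that order), and with pattern-matched members alone the cell wall median was −0.13 (adjusted p = 0.823). Salt changes were generally smaller in PI365967, and whether a list differed beyond that was not tested.

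Of 100 drawn splits of the salt labels within genotypes, 6, the real one included, called as many probe sets for this difference as the 1337 of the real one, and the highest of the others called 6442, so by this count chance was not excluded. Of the other 5 splits, 1 exchanged all 3 salt labels in PI365967 and none in Moneymaker, which by construction turns the difference into the mean of both salt effects (6442 calls). The other 4, with 2538 to 3560 calls, exchanged 2 of the 3 salt labels in PI365967 and none in Moneymaker, so that the shared response enters the difference in part. The high counts thus come with a structure of the samples, and the splits do not give a clean level of chance for this difference. For the mean of both salt effects itself, 1 of 100 splits, the real one, called as many as 6442 probe sets. The highest of the others called 3560, which argues against chance. Chance is not excluded, since only 100 of the 200 possible splits were drawn and the share cannot fall under 1 of 100. For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05, and 1 split, the real one, called as many in each. The salt effect in Moneymaker called 5756 against at most 0 in other splits, that in PI365967 4781 against 0, the genotype difference without salt 3718 against 0, and that under salt 4961 against 1.

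The first pattern weighed is that salt changed genes less in PI365967. Of 1228 probe sets whose mean salt effect was called and at least 2-fold, 879 (71.6%) changed less in PI365967 (74.7% of those that rose and 68.3% of those that fell). A probe mismatch in PI365967 that lowers its signal is argued against by the 399 with like signal in both genotypes without salt. Of these 73.7% changed less in PI365967 (exact 95% interval 69.1% to 77.9%). This interval treats probe sets as independent, which they are not, so it is likely too narrow. The normalization between arrays is argued against by 69.8% without it and 70.7% with median centring, and a single array by the ratio of the SDs of the salt changes, PI365967 over Moneymaker, which was 0.805 and at most 0.821 without any 1 array. A weaker response at 5 h in PI365967 may be a biological difference between the genotypes, but the ribosomal RNA controls also changed more under salt in Moneymaker (25S 1.86 against 0.66, 17S 0.62 against −0.20). The 17S signal was dim, with group means of −3.65 to −3.03 in log2 relative to the array median. In PI365967 1 of its salt arrays lay above all controls and 2 lay below, so its changes are uncertain. A difference in RNA composition was not tested and stays open.

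The second pattern is the set of 115 probe sets with a genotype difference of at least 4-fold in both treatments. Of these, 73.0% (84) lay lower in PI365967, as probe sequence mismatch in PI365967 would have it. The exact 95% interval of 64% to 80.9% treats probe sets as independent, which they are not, so it is likely too narrow. In both PI365967 groups 8 of the 84 lay at background. Mismatch could therefore account for part of them, PR1b1, CEVI57 and TAO2 included. The 31 that lay higher in PI365967 are not accounted for by it. A biological difference in transcript level stays open and was not tested.

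The third pattern is the lower signal of photosynthesis genes under salt, called as a list in Moneymaker (adjusted p = 0.00228; adjusted p = 0.32 with an estimated correlation) but not in PI365967 (adjusted p = 0.0746), for which a changed share of leaf and root in the pooled plants, which would raise the root-leaning list, was tested. In PI365967 its median was −0.38 (95% bootstrap interval −0.94 to −0.12) beside −0.22 for photosynthesis (−0.39 to −0.14), so neither interval reached above 0. More root alone would have raised the root-leaning list. Salt could itself lower these genes and so hide a larger root share, which the test therefore cannot exclude. The intervals resample probe sets, not plants or arrays. The call of the root-leaning list in PI365967 (adjusted p = 0.0158) was lost with an estimated correlation (0.115). That call also rests on the chosen members, since it was lost with pattern-matched members alone (0.168, median −0.29). In Moneymaker the median of the root-leaning list was −0.72 beside −0.60, but with an interval of −1.77 to 0.19. A changed share and a response to salt cannot be told apart there either, the 12 probe sets being too few and moving both ways. A biological response to salt stays open in both genotypes.

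Some of the array's own control transcripts, which the comparisons did not use, had higher signal on all 3 salt arrays than on all 3 control arrays, and others did not. In Moneymaker, salt minus control was 1.86 for 25S ribosomal RNA, 0.62 for 17S ribosomal RNA, and 1.31, 1.30 and 1.06 for the 3′ end, middle and 5′ end of ubiquitin. In PI365967 it was 1.01, 1.15 and 0.95 for the same parts of ubiquitin. Glutathione transferase 3′ signal was higher on all 3 salt arrays in Moneymaker (0.42) and lower on all 3 in PI365967 (−0.20). All 3 salt arrays lay below the controls for GAPDH 5′ in both genotypes (−0.13 and −0.36), GAPDH 3′ in PI365967 (−0.31) and phytochrome B2 in Moneymaker (−0.50), while actin 3′ did not separate them (0.03 and −0.09).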

How the results depend on the processing

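Chosen after seeing the data were the authors' second log2 values, the restriction to the probe sets the authors kept, and lists with pattern-matched members alone. All other alternatives were planned. Without normalization between arrays the counts were 3534 (salt, Moneymaker), 1983 (salt, PI365967), 292 (difference of salt effects), 1585 and 2020 (genotype without and under salt) and 3885 (mean salt effect), where the median of all probe sets moved to −0.25 for salt in Moneymaker, 0.30 for the difference, −0.22 for the genotype without salt and −0.11 for the mean salt effect. The cause of the lower counts was not tested. Arrays of the same group differed in level before normalization, with median log2 intensities of 8.651 to 9.307 among the Moneymaker controls. Median centring, which removes only such differences in level, gave 5632, 4684 and 1166 calls for the 2 salt effects and their difference. With only the brighter probe sets, above the median signal, the counts were 3539, 3001, 2329, 3094 and 3849 for all but the difference of salt effects, with fewer probe sets tested. Asking for a 2-fold change left 1540 and 1036 for the salt effects. Offsets of 1 and 64, median centring, the 25th percentile filter, an intensity trend, array weights, fits of 6 arrays, the authors' probe sets, an adjusted p under 0.01 (4666 and 3478 for the salt effects), the authors' second log2 values (5793 and 5400), the authors' SAM tables (7169 and 6475 of 8074) and an own SAM statistic (5950 and 4830) kept each count they applied to within 1.5 times. Of the 7169 and 6475 probe sets the authors' q-value took, 5153 and 4261 were also called here. Of these shared calls 5130 and 4249 had the same direction. Among all 8074 probe sets of those tables, 5242 and 4362 were called here.

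With the replicate block, counts were 5730, 4735, 1199, 3660, 4888 and 6406 for salt in Moneymaker, salt in PI365967, their difference, the genotype without and under salt and the mean salt effect, with 16 list calls. Only for the controls of the 2 genotypes did every same-number correlation exceed those of other numbers, which does not establish pairing. Without each array in turn counts ran from 5274 to 5871, 4158 to 4825, 929 to 1376, 3078 to 3820, 4365 to 4980 and 6178 to 6373, and list calls from 15 to 17. Over both salt effects camera made 16 list calls, against 1 with an estimated correlation, 37 with fry, which tests another question, and 8 with pattern-matched members alone, where 10 lists had 5 or more members.

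Named genes that changed direction in Moneymaker were LHA1 (−0.11 without normalization), TAO3 (0.00) and hqt (0.03) with median centring, IAA17 (0.00) without salt replicate 1, TAO3 without control replicate 2 (0.07) and without salt replicate 3 (0.04), and hqt without salt replicate 2 (0.01). Over the arrays left out in turn, values ran from −0.14 to 0.07 for TAO3, from −0.34 to 0.00 for IAA17 and from −0.15 to 0.01 for hqt. None of these was called in Moneymaker. In the authors' second log2 values they were TFT6 (0.00), hqt (0.08) and CycB2 (0.32, adjusted p = 0.015) in Moneymaker, and TFT7 (0.03), LHA2 (0.02) and CycB2 (0.69, adjusted p = 3.03e-05) in PI365967. The causes were not tested. Among single genes 55 calls were lost and 33 gained over all alternatives other than left-out arrays, counted once per gene, comparison and alternative. The 9 changes of direction under these alternatives, those of CycB2 among them, are not in these counts. Signal over background limits dim genes: PRK2 lay at background in all 4 groups, so it has no fold.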

Other observations

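All tests in this part were set before their results were seen, except the use of the authors' second log2 values, which was chosen after the data were seen. Psy1, the phytoene synthase gene of carotenoid synthesis, rose by 0.48 under salt in Moneymaker and by 1.35 in PI365967, where it lay 2.47 lower than in Moneymaker without salt, and its call in Moneymaker was lost without any 1 of 2 arrays (0.39 to 0.41) and without normalization between arrays (0.29, adjusted p = 0.402). HMGR, of isoprenoid synthesis, fell by 1.35 in PI365967 and by 0.44 in Moneymaker, where its call was lost without any 1 of 4 arrays (−0.45 to −0.29). The Moneymaker call was also lost with array weights (−0.21, adjusted p = 0.24) and with only the arrays of the groups compared (adjusted p = 0.0732). In the authors' second log2 values the fall was not called either (−0.29, adjusted p = 0.0589). PPCK1 rose by 1.43 in Moneymaker and 2.44 in PI365967 and lay 2.11 lower in PI365967 than in Moneymaker without salt. Solute genes had 5 of 16 probe sets with a larger change towards a rise in PI365967 and none the other way (IMP3 0.51; camera adjusted p = 0.0868), or 6 adjusted over the list alone. In ion transport 2 of 6 probe sets had a positive difference of salt effects (LHA1, LHA2) and 2 a negative one.

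One hypothesis was that genes that salt raised in Moneymaker were already higher in unstressed PI365967. With each Moneymaker control array in turn kept for the genotype difference and the other controls used for the salt effect, the median genotype difference of the probe sets that rose at least 2-fold (795 to 866) exceeded that of all probe sets by 0.06, −0.06 and 0.09. The lowest of these, −0.06, lies below 0, and all 3 are under 0.1, which argues against the hypothesis for these probe sets as a set. For the probe sets that fell at least 2-fold, the same measure was 0.07, 0.28 and −0.03. Such a median therefore moved with the control array kept, which limits the test.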
